A study of Homo sapiens with 12 samples.

How the data were processed

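RNA from Jurkat cells, a T-lymphocyte leukemia line, was measured on 12 Affymetrix HG-U133A_2 arrays, alone (plain RNA) or with added globin RNA (spiked RNA). Per the labels, both RNAs came from a commercial set of globin-reduction RNA controls. Biotinylated cRNA was made with the MessageAmp II kit (Ambion), and biotinylated cDNA with the Ovation Biotin System (NuGEN) from 50 ng of RNA. Each of the 4 combinations had 3 replicate arrays. Nothing in the labels says that replicates were separate cultures, so they may be technical, and the limma p-values measure only the spread between these arrays. The labels do not say which globin chains were added.

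The deposited values are an intensity per probe set, the MAS5 signal on a linear scale in arbitrary units, per the submitters' processing notes. The MAS5 version and scaling target were not stated. The mean of each array after trimming 2% from each end was 100; detection calls were not used here. Levels were compared within a probe set between groups. Of the 22277 probe sets, 62 controls were left out of the tests, which leaves 22215. A single gene symbol was given for 19064 of these, several symbols for 1043 and none for 2108. Of the probe sets with 1 symbol, 19052 were matched to the gene table and 0 symbols were changed. Probe sets with several symbols were named by the family, such as both α-globin genes. Genome coordinates were not used here.

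The test was limma 3.58.1 in R 4.3.3 (lmFit, contrasts, eBayes with trend) on log2(signal + 16), with the 12 arrays in 1 fit of 4 group means. All p-values of this test are two-sided and adjusted by Benjamini and Hochberg over the 22215 probe sets, with 0.05 as the threshold. Folds in the text are log2 fold changes from this fit, and levels are mean signals ± SD over 3 arrays. Where a group read near 0, the size of a log2 fold change is set by the pseudocount, and the levels are given. The 5 contrasts were the globin RNA effect (spiked against plain) with each target, the difference of these effects (cDNA minus cRNA), and cDNA against cRNA target with each RNA. The size of the globin RNA effect was the root mean square log2 fold change over probe sets that are not globin. Its difference between targets was tested by an exact two-sided permutation of the globin label within each preparation.

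Gene lists were tested with camera, with an inter-gene correlation of 0.01, on 1 probe set per gene over 11963 genes. The probe set with the highest mean over the 12 arrays stood for its gene, and p was adjusted over 16 lists per contrast. The lists were the globin family, erythroid genes other than globins, T cell, B cell, myeloid, liver, muscle, neuron and testis markers, T-lineage leukemia regulators, ribosomal proteins, replication-dependent histones, oxidative phosphorylation, proteasome, glycolysis and cell cycle. A list's shift is its median log2 fold change minus that of all genes. Probe sets were also grouped by the suffix of their identifier, where _x_at marks probes that can match other transcripts. Shares were compared by Fisher's exact test, which treats probe sets as independent although they share arrays and some share genes.

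The named genes follow a rule. All globin probe sets are named. For each globin RNA effect and for cDNA against cRNA with plain RNA, the 8 highest and the 8 lowest log2 fold changes were taken. For the difference of effects, the 5 highest and 5 lowest were taken. These probe sets had 1 symbol, passed the threshold, had groups that did not overlap, and had a higher group mean at or above the median of all group means (5.08 on the log2 scale). From each list, up to 3 members past the threshold with the largest changes were added, or, where none passed, the 2 with the highest mean. Control probe sets for ACTB, GAPDH and the added bacterial transcripts were included. The comparisons, lists, naming rule and alternatives other than those named below as added were fixed before the data were examined.

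Instrument records placed the arrays in 4 scan sessions, parted by gaps of 30 minutes or more. All cRNA arrays were scanned on 1 day and all cDNA arrays on another. Each session held arrays of both RNAs, so session was also fitted as a block, and the globin RNA effects were refitted within sessions, where a lone array of a group was assumed to vary like the others. Alternatives were pseudocounts of 1 and 64, quantile normalization, equal array medians, leaving out the lower 50% of probe sets by mean signal, eBayes without trend, fits to only the arrays compared, blocks for replicate number and for session, each array left out in turn, an estimated correlation in camera, and the mean of all probe sets of a gene. Scaling to the 18 bacterial and phage hybridization controls, leaving out 2 cRNA arrays with an incomplete fluidics log, and the fits within sessions were added after seeing the data.

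The procedure was tested on simulated data with 100 probe sets changed at each size, built on the spread of these arrays. On cRNA arrays it recovered 100 at a log2 fold change of 1 and 82 at 0.5, with 9 false calls. On cDNA arrays it recovered 100 and 81, with 12 false calls. Noise was drawn independently for each probe set from the variances of the fit, without shifts of whole arrays or sessions. These counts therefore do not show how many calls on the real arrays were false. With the proteasome list raised by 0.3, camera gave an adjusted p of 2.73e-83 and called 0 other lists. On the real arrays the ribosomal list had an estimated correlation of 0.5. The simulation does not show how often camera makes false calls for lists correlated that strongly. The number of arrays limits the precision.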

Results

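The series compared cross-hybridization between cRNA and cDNA target. Jurkat RNA, from a T-lymphocyte leukemia line, was hybridized plain or spiked with globin RNA in either target form, with 3 arrays in each of 4 groups. The median signal per array was 21.3 ± 0.0416 for plain RNA as cRNA, 25 ± 0.364 for spiked RNA as cRNA, 13.3 ± 0.170 for plain RNA as cDNA and 13.4 ± 0.228 for spiked RNA as cDNA (arbitrary units, SD over 3 arrays). Replicate arrays correlated over probe sets with r of 0.992 to 0.997, where probe sets are not independent replicates. The median SD of a probe set between replicates was 0.072, 0.0987, 0.0799 and 0.0891 on the log2 scale, in the same order. The number of arrays limits the precision of the values that follow.

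The first question was what added globin RNA changed on cRNA arrays. HBB, the β chain of adult hemoglobin, rose from a mean of 0.37 ± 0.164 to 5614 ± 258 (SD, n = 3, probe set 209116_x_at). The 9 probe sets for HBB and both α-globin genes had means of 0.37 to 12.1 in plain RNA and 3611 to 5614 in spiked RNA, and all 9 rose. Of the 8 probe sets for other globins, 7 rose. HBD, the δ chain of a minor adult hemoglobin, rose from 0.523 ± 0.302 to 153 ± 17.5, and HBE1, the embryonic ε chain, from 0.533 ± 0.331 to 51.6 ± 7.52 (205919_at). The 3 probe sets annotated to both γ-globin genes, the fetal chains, reached means of 218 ± 45.9, 145 ± 20.9 and 97.6 ± 39.9. HBQ1, the θ chain, reached 25.9 ± 17.2, whereas HBZ, the embryonic ζ chain, had a mean of 2.79 in spiked RNA and did not pass the test. Of the 5 globin genes with a probe set of their own, 4 rose (5 adjusted over the list alone), and the list shift was 1.96, with camera adjusted p = 4.35e-05 and adjusted p = 0.0221 with an estimated correlation. Its shift was 1.99 with session as a block and 2.13 and 1.85 within the 2 cRNA sessions.

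Genes that are not globins moved as well. GIT1, a scaffold protein that acts on ARF GTPases, rose from 44.4 ± 4.19 to 361 ± 62.5, and ADAP1, an adaptor with an ARF GTPase-activating domain, from 50.3 ± 7.36 to 284 ± 17 on 90265_at. GLUL, glutamine synthetase, rose from 134 ± 0.743 to 680 ± 26.8 on 217202_s_at, while its other probe sets had log2 fold changes of -0.24 and 0.03 and did not pass. COL1A1, a chain of type I collagen, rose from 14.7 ± 2.99 to 120 ± 13.5 on 217430_x_at. EPOR, the erythropoietin receptor, rose from 62.9 ± 12.8 to 327 ± 51.7 on 396_f_at, and its 4 other probe sets had smaller log2 fold changes of 0.04 to 0.78. RPS9, a protein of the small ribosomal subunit, fell from 1571 ± 6.78 to 202 ± 12.9 on 214317_x_at, against a log2 fold change of -0.22 on its other probe set. RARS1, arginyl-tRNA synthetase, fell from 452 ± 22.7 to 60.3 ± 4.03. EEF1D, a subunit of translation elongation factor 1, fell from 716 ± 45.4 to 118 ± 3.82 on 203113_s_at, and its other probe sets had log2 fold changes of -1.89, -0.44 and 0.61. CASP6, an apoptotic caspase, fell by 1.83 on the log2 scale on 211464_x_at. TOR1AIP2, which binds torsins, AKTIP and CCNL2, a cyclin of splicing bodies, fell by 1.73, 1.78 and 1.69. AIF1, a calcium-binding protein, fell by 1.97 on 209901_x_at, and its other probe sets had log2 fold changes of -0.71, 0.02 and 0.14, of which the first passed.

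Among ribosomal protein genes, 35 of 52 measured members rose and 10 fell (36 and 10 adjusted over the list alone), a split that became 10 and 22 after quantile normalization, 31 and 13 with equal array medians and 1 and 49 with hybridization control scaling. RPL3 and RPL35, proteins of the large subunit, fell by 1.10 each on the log2 scale, and RPLP2, an acidic stalk protein, rose by 0.80, against -0.10 on its other probe set. The list shift was 0.31, with camera adjusted p = 3.84e-04 and adjusted p = 0.568 with an estimated correlation. It was 0.30 with session as a block and 0.30 and 0.31 within sessions. The shift turned to -0.06 after quantile normalization, and with hybridization control scaling its median was 0.02 while the test pointed down. Oxidative phosphorylation genes, which encode the respiratory chain and ATP synthase, rose for 10 of 49 members and fell for 21 (12 and 24 adjusted over the list alone), a split that became 5 and 29 with equal array medians and 0 and 48 with hybridization control scaling. CYC1, cytochrome c1, and COX7C, a subunit of cytochrome c oxidase, had log2 fold changes of -1.28 and -1.25. The list shift was -0.18, with camera adjusted p = 5.28e-03 and adjusted p = 0.0558 with an estimated correlation. It was -0.22 with session as a block and -0.17 and -0.19 within sessions.

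The remaining lists did not pass camera on cRNA arrays with the main scaling. Of T cell genes, 8 of 18 rose and 3 fell (8 and 3 adjusted over the list alone). ZAP70, a kinase of T cell receptor signaling, fell by 1.17 on the log2 scale. T-lineage leukemia regulators rose for 9 of 16 members and fell for 2 (9 and 2 adjusted over the list alone), with NOTCH1, a receptor mutated in this leukemia, at 0.96 and STIL at -0.55. Cell cycle genes rose for 10 of 26 and fell for 7 (11 and 7 adjusted over the list alone), with E2F1, a transcription factor of S-phase entry, at 1.33 and PLK1, a mitotic kinase, at -0.82. Glycolysis genes rose for 10 of 17 and fell for 5, and proteasome genes rose for 8 of 27 and fell for 10, with the same counts adjusted over the list alone. Replication-dependent histones rose for 7 of 32 and fell for 2 (6 and 1 adjusted over the list alone). These splits turned downward with hybridization control scaling, to 0 and 16 for T cell, 1 and 10 for regulator, 1 and 25 for cell cycle, 0 and 16 for glycolysis and 3 and 10 for histone genes. The proteasome split became 0 and 27 with this scaling and 4 and 13 with equal array medians, and cell cycle (6 and 9) and histone genes (1 and 4) also turned downward with equal array medians. The proteasome list passed camera with the mean of all probe sets (adjusted p = 0.0333). With hybridization control scaling, camera called the T cell (adjusted p = 0.0294), cell cycle (9.21e-04), proteasome (5.31e-05) and glycolysis genes (0.0273) as lower than other genes, and histone genes (0.0138) as higher. Histone genes read near 0, with median signals of 3.82 in plain and 6.09 in spiked RNA. This scaling moves low signals less than high ones, so such calls can come from it alone.

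Markers of other cell types also moved on cRNA arrays, where 5514 of all 22215 probe sets rose and 3407 fell. The median signal of these markers was low, 2.71 in plain and 5.17 in spiked RNA. Of the 5552 probe sets of lowest signal that are not globin, 954 rose and 49 fell. Of the 5548 next in signal, 1922 rose and 279 fell. Whether the markers differed from other probe sets of like signal was not tested. Over the 7 lists of erythroid, B cell, myeloid, liver, muscle, neuron and testis genes, 36 of 114 members rose and 1 fell, against 15 and 5 after quantile normalization, 16 and 9 with equal array medians and 19 and 20 with hybridization control scaling. The numbers that rose were 4 of 12 erythroid, 4 of 13 B cell, 3 of 16 myeloid, 8 of 19 liver, 8 of 19 muscle, 4 of 17 neuron and 5 of 18 testis genes. Adjusted over the list alone they were 4, 3, 2, 8, 8, 1 and 4. With hybridization control scaling, camera called 6 of these lists as higher than other genes, namely erythroid (adjusted p = 5.64e-03), B cell (0.0404), liver (3.37e-04), muscle (6.98e-05), neuron (2.74e-03) and testis genes (5.31e-05). This scaling moved the median log2 fold change of all probe sets by -0.467, which members near 0 could not follow because of the pseudocount of 16. The list shifts of 0.44 to 0.56 are near that size, so these calls are no evidence that the markers rose. TTR, the thyroxine carrier transthyretin, rose from 0.907 ± 0.176 to 31.3 ± 18.6, and NPPA, atrial natriuretic peptide, from 5.14 ± 2.98 to 44.3 ± 13.8. RHAG, a glycoprotein of the red cell Rh complex, rose from 2.14 ± 1.14 to 16.1 ± 2.84. TNNT1, troponin T of slow muscle, was the 1 that fell, from 104 ± 3.90 to 38.6 ± 0.995.

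In total 5514 probe sets rose and 3407 fell with limma, of which 168 and 159 changed at least 2-fold, and 8905 of the called probe sets were not globins. The split was 3605 and 3587 after quantile normalization, 2925 and 5884 with equal array medians, and 1606 and 12724 with hybridization control scaling. Equal medians moved the median log2 fold change of all probe sets by -0.137, and hybridization control scaling by -0.467. Probe sets with the _x_at suffix rose in 35% of 2416, against 23.8% of 11769 with the _at suffix (Fisher's exact test, p = 2.47e-29). They also fell more often, in 15.0% against 12.7% (Fisher's exact test, p = 0.00321). This test takes probe sets as independent, so its p does not measure the spread between arrays. The counts were 5362 and 3242 with session as a block, and 3453 and 2195 in session 1 and 2941 and 2014 in session 2. Of the called probe sets 61.8% rose, against 33.2% with equal medians and 46.3% (2786 and 3225) without the lower 50% of probe sets by signal.

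**Figure D1:**
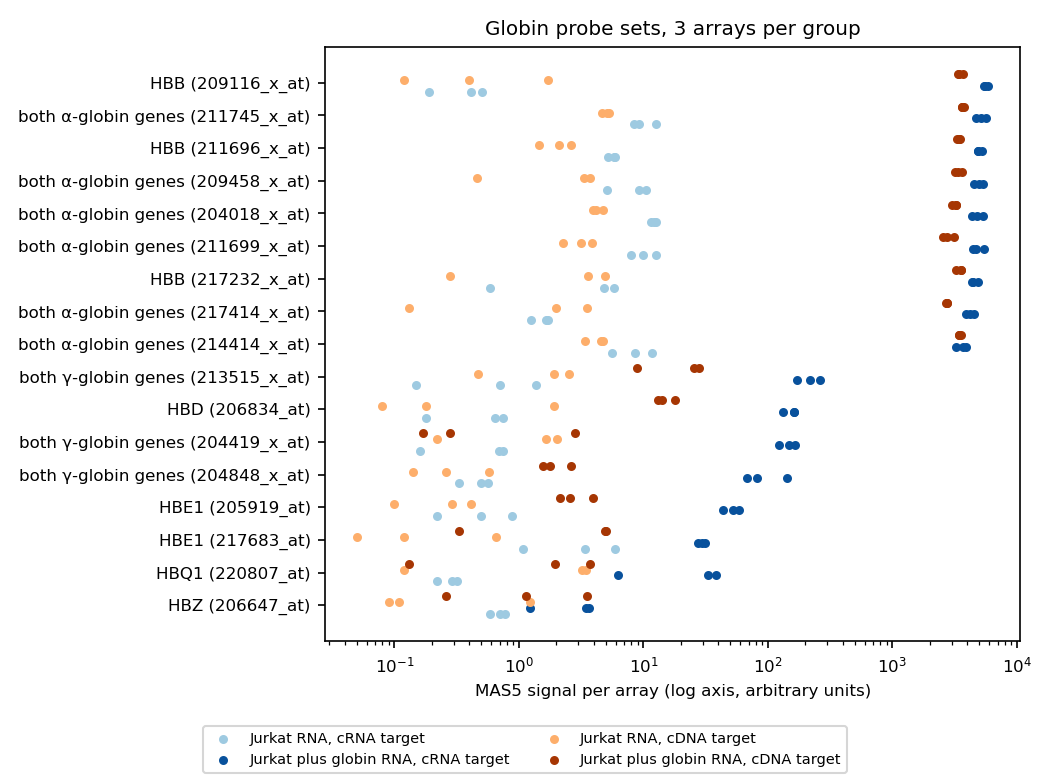
MAS5 signal per array (log axis, arbitrary units) of the 17 globin probe sets, 1 point per array and 1 color per group. The 9 probe sets for HBB and both α-globin genes have means of 2737 to 5614 in spiked RNA with either target, whereas the other 8 have means of at most 218 on cRNA arrays and at most 20.9 on cDNA arrays.

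The second question was what added globin RNA changed on cDNA arrays. HBB rose from 0.743 ± 0.849 to 3490 ± 149 (SD, n = 3, 209116_x_at). The 9 probe sets for HBB and both α-globin genes all rose, from means of 0.743 to 5.02 in plain RNA to 2737 to 3657 in spiked RNA. HBD rose from 0.72 ± 1.02 to 15.1 ± 2.58, and 1 probe set for both γ-globin genes reached 20.9 ± 10.4. The other 6 globin probe sets did not pass the test, among them HBE1 at a mean of 2.88 and HBQ1 at 1.95 in spiked RNA. Of the 5 globin genes in the list, 2 rose (2 adjusted over the list alone), and the list shift was 0.21, with camera adjusted p = 5.64e-10 and adjusted p = 1.28e-03 with an estimated correlation. It was 0.21 with session as a block and 0.24 and 0.28 within the 2 cDNA sessions. The mean shift of the list was 1.75, since HBB rose far more than the other members. The camera call therefore does not describe a rise shared by the list.

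Changes of other genes on cDNA arrays were small. FLII, a gelsolin-family actin regulator, rose from 24.0 ± 7.28 to 45.7 ± 4.34, and KCNAB2, a potassium channel β subunit, from 77.8 ± 18.8 to 123 ± 5.86. RNH1, the ribonuclease inhibitor, rose from 31.5 ± 4.75 to 53.1 ± 2.60. VPS51, of a Golgi tethering complex, FLOT1, a membrane raft protein, SPTAN1, a spectrin, and DDRGK1 rose by 0.52, 0.51, 0.50 and 0.50 on the log2 scale. PAGR1 fell from 135 ± 2.34 to 76.0 ± 13.4, and YTHDC1, a reader of methylated RNA, from 122 ± 17.2 to 76.1 ± 0.972. RIPK4, a kinase of keratinocyte differentiation, ECD, CYTH1, an exchange factor for ARF GTPases, SLC5A3, an inositol transporter, ZMIZ1 and PRPS1, a nucleotide synthesis enzyme, fell by 0.51, 0.49, 0.48, 0.47, 0.46 and 0.45 on the log2 scale. Other probe sets of FLII, KCNAB2, RNH1, YTHDC1, CYTH1, PRPS1, SLC5A3 and SPTAN1 did not pass, and 1 for SPTAN1 had a log2 fold change of -0.33.

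Ribosomal protein genes rose for 2 of 52 members on cDNA arrays with limma and fell for 0 (46 and 0 adjusted over the list alone, and the same at an unadjusted p under 0.05). RPL36 rose by 0.25 and RPL27 by 0.23 on the log2 scale. The list shift was 0.17, with camera adjusted p = 5.63e-35 and adjusted p = 0.0662 with an estimated correlation, but it turned to -0.02 after quantile normalization and was 0.02 without passing under hybridization control scaling. It was 0.19 with session as a block and 0.22 and 0.18 within sessions. Oxidative phosphorylation genes rose for 2 of 49 with limma and fell for 0 (14 and 1 adjusted over the list alone, 20 and 3 at an unadjusted p under 0.05), with ATP5ME, a subunit of ATP synthase, at 0.29 and NDUFB8, a subunit of complex I, at 0.25. The shift was 0.08, with camera adjusted p = 4.08e-09 and adjusted p = 1.28e-03 with an estimated correlation, but it turned to -0.05 with hybridization control scaling. It was 0.09 with session as a block and 0.06 and 0.10 within sessions. Glycolysis genes rose for 2 of 17 with limma and fell for 0 (8 and 0 adjusted over the list alone, 9 and 0 at an unadjusted p under 0.05), with PKM, pyruvate kinase, at 0.28 and ALDOA, aldolase, at 0.23. The shift was 0.12, with camera adjusted p = 1.9e-06 and adjusted p = 0.0198 with an estimated correlation, but it turned to -0.02 with hybridization control scaling. It was 0.14 with session as a block and 0.10 and 0.13 within sessions. Of T cell genes limma called 0 of 18 and of leukemia regulators 0 of 16 on cDNA arrays (1 and 2 were higher adjusted over the list alone), and at an unadjusted p under 0.05 there were 3 higher and 1 lower T cell genes and 4 higher and 3 lower regulators. TRBC1 and CD3D, of the T cell receptor complex, had log2 fold changes of 0.18 and 0.10, while another TRBC1 probe set rose by 0.23 on the log2 scale, and LEF1 and MYB, transcription factors, 0.17 and 0.15. Limma called 0 of 27 proteasome, 0 of 26 cell cycle and 0 of 32 histone genes, of which 7, 4 and 0 were higher and 3, 0 and 2 lower at an unadjusted p under 0.05. Of the 114 markers of other cell types, limma called 0, and 1 had an unadjusted p under 0.05. Camera called all 7 of these lists as higher than other genes on cDNA arrays with hybridization control scaling (adjusted p from 4.49e-03 to 0.0416), and proteasome (2.59e-04) and cell cycle genes (3.61e-03) as lower. That scaling moved the median of all probe sets by -0.061, which markers near 0 could not follow because of the pseudocount. Their list shifts of 0.058 to 0.081 are about that size, so these calls are no evidence that the markers rose. The scaling moves high signals more than low ones, so the proteasome and cell cycle calls can also come from it alone.

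In total 70 probe sets rose and 53 fell on cDNA arrays with limma, of which 10 and 0 changed at least 2-fold, and 112 were not globins. At an unadjusted p under 0.05 there were 2523. The split was 60 and 32 after quantile normalization, 64 and 55 with equal array medians and 13 and 891 with hybridization control scaling. Probe sets with the _x_at suffix rose in 0.993%, against 0.144% with the _at suffix (Fisher's exact test, p = 2.44e-09), and fell in 0.166% against 0.187%. The counts were 71 and 37 with session as a block, 9 and 1 within session 3 and 10 and 0 within session 4, where 1205 and 924 had an unadjusted p under 0.05. Of the named probe sets called on cDNA arrays, the 9 for HBB and both α-globin genes kept the call within each of these sessions and the other 23 lost it. The counts were 12 and 1 in a fit to only the cDNA arrays and 37 and 29 with eBayes without trend. They were 185 and 128 without the lower 50% of probe sets by signal. Single arrays moved them. The counts were 28 and 17 without plain cDNA replicate 1, 32 and 7 without replicate 2 and 209 and 66 without replicate 3. They were 36 and 23 without spiked cDNA replicate 1, 24 and 14 without replicate 2 and 43 and 36 without replicate 3. Of the probe sets that fell, 33 were called without plain cRNA replicate 1 and 28 without replicate 2, arrays that share only the estimate of spread.

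The third question was whether the globin RNA effect differed between targets, as the effect on cDNA minus that on cRNA arrays. RPS9, EEF1D, RARS1, CASP6 and TOR1AIP2, which fell on cRNA arrays, had differences of 3.00, 2.61, 2.51, 2.00 and 1.77 on the log2 scale. RPS9 had means of 453 ± 17.1 in plain and 499 ± 41.7 in spiked RNA as cDNA, and TOR1AIP2 of 1071 ± 43.2 and 1102 ± 38.4 (SD, n = 3). HBD, GIT1, ADAP1, EPOR and COL1A1 had differences of -2.45, -2.33, -2.19, -2.14 and -2.05. ADAP1 had means of 20.9 ± 5.74 and 20.6 ± 2.42 as cDNA, and EPOR of 5.26 ± 3.79 and 4.85 ± 1.16. Each of these 10 passed limma, with adjusted p from 3.82e-11 to 5.83e-06. Of the 8 globin probe sets other than α and β, 7 rose less on cDNA arrays.

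Oxidative phosphorylation genes had a higher effect on cDNA arrays for 23 of 49 members and a lower one for 7 (27 and 7 adjusted over the list alone). COX7C, CYC1 and NDUFA1, a subunit of complex I, had differences of 1.39, 1.33 and 0.82 on the log2 scale. The list shift was 0.25, with camera adjusted p = 1.42e-05 and adjusted p = 0.0106 with an estimated correlation. It was 0.29 with session as a block, and 0.24 and 0.27 between the first and between the second sessions. The effect was lower for 4 of 5 globin genes (4 adjusted over the list alone), and the list shift was -1.21, with camera adjusted p = 2.89e-03 and adjusted p = 0.0529 with an estimated correlation. It was -1 with session as a block, and -0.33 and -1.66 between sessions, and the call was lost with pseudocount 1 (shift -3.17, adjusted p = 0.349) and after quantile normalization (shift -1.07, adjusted p = 0.121). With the mean of all probe sets the proteasome list passed (shift 0.15, adjusted p = 0.0115). With hybridization control scaling camera called ribosomal (3.74e-06), proteasome (1.21e-04), glycolysis (0.0274) and cell cycle genes (1.67e-03) as higher in this difference than other genes. It called erythroid, liver, muscle, neuron and testis genes and histones as lower (adjusted p from 4.24e-04 to 0.0102). That scaling moved the median of all probe sets by 0.367, which lists near 0 could not follow because of the pseudocount. Their shifts of -0.25 to -0.41 can come from this alone. The scaling moves high signals more than low ones, so the calls of lists as higher can also come from it alone. Of the 114 markers of other cell types, the effect was higher on cDNA arrays for 1 and lower for 16, against 9 and 8 with hybridization control scaling.

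In total the effect was higher on cDNA arrays for 2260 probe sets and lower for 3366, of which 169 and 170 differed at least 2-fold. The split was 2451 and 2353 after quantile normalization, 3745 and 1699 with equal array medians and 9776 and 920 with hybridization control scaling, and 2133 and 3205 with session as a block. It was 2292 and 2154 without the lower 50% of probe sets by signal. Equal medians moved the median of all probe sets by 0.133, and hybridization control scaling by 0.367. Over probe sets that are not globin, the root mean square log2 fold change was 0.344 on cRNA and 0.118 on cDNA arrays. The difference was 0.226 (exact two-sided permutation p = 0.1, over 100 combinations). Regrouping the cDNA arrays breaks up any real effect on them and so widens the difference. With such an effect p cannot fall under 0.1, so this p does not show that the sizes were alike. The 10 of 100 combinations as large all kept the real cRNA groups, and with cRNA arrays regrouped the highest was 0.0642. Across probe sets that are not globin the 2 effects had r = 0.072, where probe sets are not independent replicates. They shared 30 that rose against 14.6 by chance and 17 that fell against 8.13 by chance, while 29 moved in opposite directions. No chance count was computed for the opposite calls, so the shared counts alone do not show that the 2 effects agreed.

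**Figure D2:**
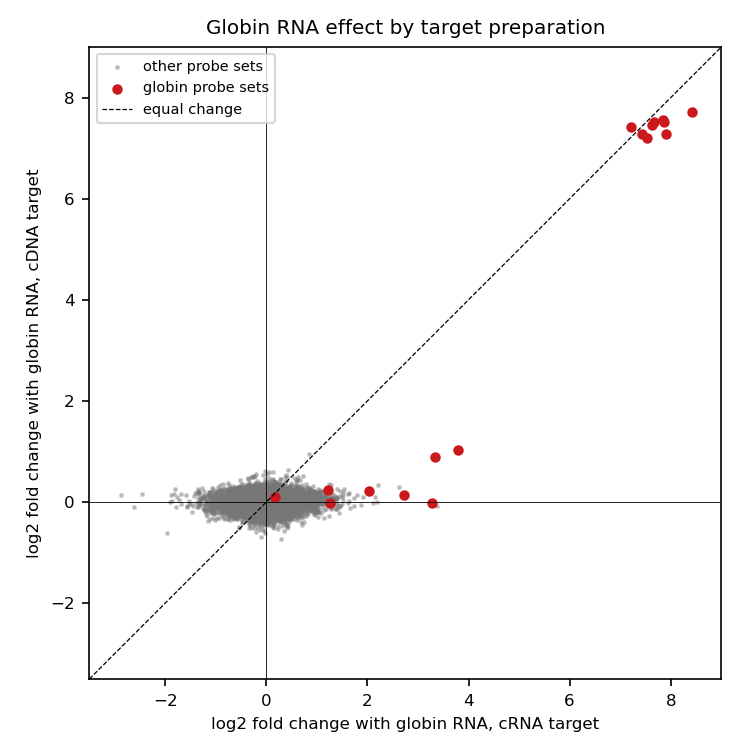
Log2 fold change of spiked against plain RNA for each probe set, with cRNA target on the horizontal and cDNA target on the vertical axis. The root mean square over probe sets that are not globin is 0.344 along the horizontal and 0.118 along the vertical axis.

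The fourth question was how cDNA and cRNA target read the same plain RNA. H3C3, a replication-dependent histone, had a mean of 760 ± 46.3 as cDNA against 1.62 ± 1.01 as cRNA (SD, n = 3). TCF3, the E2A transcription factor, read 1687 ± 59.3 against 31.4 ± 3.75 on 202648_at, while its 12 other probe sets had log2 fold changes of -1.07 to 1.07. RPLP2 read 1897 ± 113 against 38.0 ± 1.34, and CGGBP1, a binder of CGG repeats, 609 ± 12.0 against 4.74 ± 0.953. LSM4, an RNA-processing protein, and ARF6, a GTPase of membrane traffic, were higher as cDNA by 5.17 and 5.16 on the log2 scale on 1 probe set each, and another probe set of each was lower, at -2.95 and -2.03. RPS10 and RPL37A were higher by 4.94 and 4.88, whereas their other probe sets were lower, at -0.36 to -0.66 and at -0.51 and -0.55. UQCRC1, a core protein of respiratory complex III, read 28.0 ± 4.02 as cDNA against 718 ± 24.7 as cRNA. UBE2S, a ubiquitin-conjugating enzyme of mitosis, read 91.5 ± 3.2 against 1198 ± 20.8. EIF5A, a translation factor, read 70.0 ± 4.42 against 876 ± 24.3, with other probe sets at -0.73 and -0.08 on the log2 scale. ABHD17A, a depalmitoylase, SUMO4, CYBA, an NADPH oxidase subunit, and CDIPT, phosphatidylinositol synthase, were lower as cDNA, with log2 fold changes of -3.60, -3.47, -3.36 and -3.28. WAS, an actin regulator of blood cells, was lower by 3.22 on 38964_r_at and higher by 0.56 on its other probe set.

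T cell genes were higher as cDNA for 4 of 18 members and lower for 14 (4 and 14 adjusted over the list alone), also with 4 and 13 after quantile normalization, 4 and 11 with equal array medians and 0 and 17 with hybridization control scaling. LCK, the T cell receptor kinase, read 318 ± 19.2 as cDNA against 1434 ± 32.3 as cRNA, and CD247, the receptor ζ chain, 59.5 ± 6.65 against 307 ± 4.30. The shift was -0.82, with camera adjusted p = 0.0409 and adjusted p = 0.12 with an estimated correlation. Glycolysis genes were higher for 1 of 17 and lower for 13 (1 and 13 adjusted over the list alone), with TPI1, triosephosphate isomerase, at -2.24 and 0.10 on another probe set, and HK1, hexokinase, at -2. Their shift was -1.02, with camera adjusted p = 3.1e-03 and adjusted p = 0.105 with an estimated correlation. Cell cycle genes were higher for 6 of 26 and lower for 19 (7 and 19 adjusted over the list alone), with MCM5, a replication helicase subunit, at -2.22. Their shift was -0.59, with camera adjusted p = 0.048, adjusted p = 0.105 with an estimated correlation and 0.182 with the mean of all probe sets (shift -0.67). Oxidative phosphorylation genes were higher for 9 of 49 and lower for 32 (11 and 32 adjusted over the list alone), a split that became 20 and 21 with equal array medians. CYC1 was at -3.15 and NDUFV1, a subunit of complex I, at -1.85. Their shift was -0.25, with camera adjusted p = 0.0206 and adjusted p = 0.105 with an estimated correlation. The mean of all probe sets also ended the calls for T cell (shift -0.55, adjusted p = 0.103) and oxidative phosphorylation genes (shift -0.19, adjusted p = 0.371).

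Replication-dependent histones were higher as cDNA for 10 of 32 members and lower for 5 (10 and 5 adjusted over the list alone). The split was 13 and 4 after quantile normalization and 4 and 20 with hybridization control scaling. H1-3 and H1-2, linker histones, were higher by 2.57 and 1.91 on the log2 scale. The shift was 0.17, with camera adjusted p = 0.0397 and adjusted p = 0.105 with an estimated correlation. Ribosomal protein genes were higher for 8 of 52 and lower for 32 (10 and 32 adjusted over the list alone) but turned to 24 and 12 with equal array medians, with RPL27A at 4.01 and RPL35 at -1.41, and did not pass camera (adjusted p = 0.137). Their median shift was -0.17 and their mean shift 0.06. They passed with hybridization control scaling (shift -1.22, adjusted p = 1.76e-07). Proteasome genes were higher for 6 of 27 and lower for 18 (6 and 18 adjusted over the list alone, camera adjusted p = 0.112), a split that became 11 and 12 with equal array medians. This list passed after quantile normalization (shift -0.49, adjusted p = 2.6e-03) and with hybridization control scaling (shift -1.26, adjusted p = 1.27e-05). Hybridization control scaling moves high signals more than low ones, so the ribosomal and proteasome calls with it can come from this alone. T-lineage leukemia regulators were higher for 6 of 16 and lower for 5 (6 and 5 adjusted over the list alone), against 1 and 13 with hybridization control scaling. RAG1, a recombinase of receptor gene assembly, read 267 ± 8.39 as cDNA against 17.6 ± 3.61 as cRNA, and MYC, a growth regulator, 71.3 ± 6.97 against 412 ± 22.7. GATA3, a T cell transcription factor, was at -1.75 and -1.27 on 2 probe sets and at 1.47 on another. Of the 114 markers of other cell types, 2 were higher and 27 lower, but 62 were higher and 9 lower with equal array medians, which shift values near 0 like all others. Camera with hybridization control scaling called the erythroid, myeloid, liver, muscle, neuron and testis lists (adjusted p from 7.23e-04 to 0.0303) and the globin list (0.0152) as higher than other genes. That scaling moved the median of all probe sets by -1.069, which lists near 0 could not follow because of the pseudocount. Their shifts of 0.77 to 1.24 are near that size, so these calls do not show that cDNA read these genes higher.

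**Figure D3:**
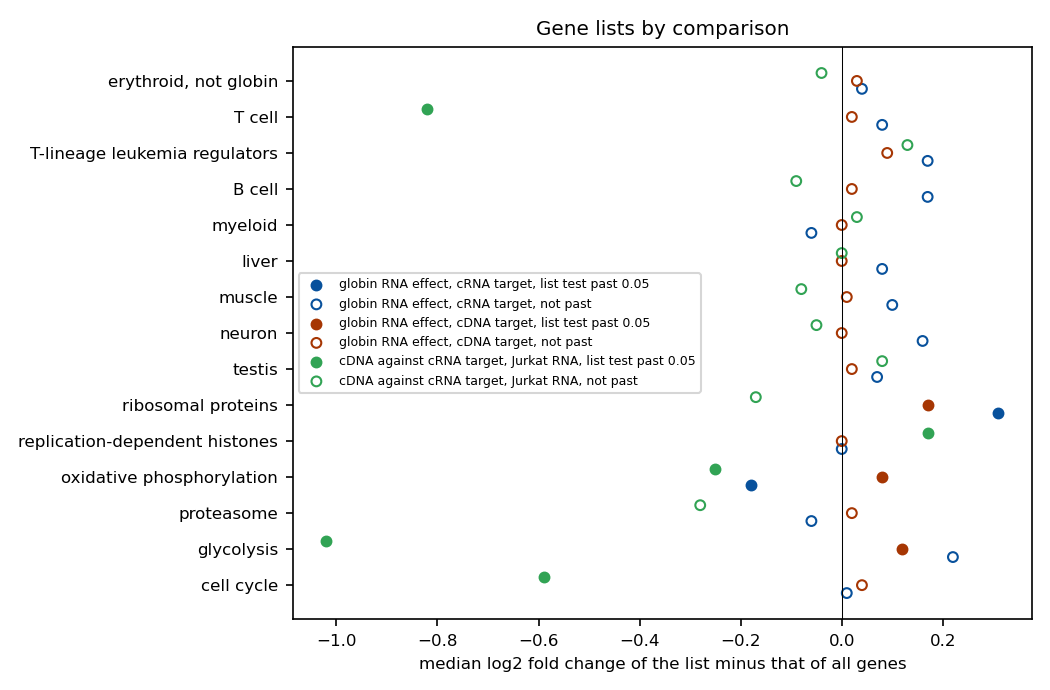
Median log2 fold change of each gene list except the globin family, minus that of all genes (horizontal axis). Shown are the globin RNA effect with each target and cDNA against cRNA target in plain RNA. Filled points mark where camera passed 0.05 with a correlation of 0.01. An estimated correlation ends the calls for the ribosomal list (adjusted p = 0.568 on cRNA and 0.0662 on cDNA arrays). It also ends those for oxidative phosphorylation on cRNA arrays (0.0558) and the globin list in the difference of effects (0.0529, not shown). Between targets it ends the calls for all 5 lists in plain RNA (0.105 to 0.12) and for glycolysis in spiked RNA (0.302, not shown). The ribosomal shifts of 0.31 (cRNA) and 0.17 (cDNA) turn to -0.06 and -0.02 after quantile normalization, and the cDNA shifts of oxidative phosphorylation (0.08) and glycolysis (0.12) turn to -0.05 and -0.02 with hybridization control scaling.

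Control probe sets for a 3′, a middle and a 5′ part of ACTB, β-actin, differed in how both targets read them. The 3′ probe set read 2634 ± 284 as cDNA against 2621 ± 70.9 as cRNA in plain RNA. The middle one read 1048 ± 6.25 against 2677 ± 63.5, and the 5′ one 384 ± 9.98 against 2360 ± 66.6 (SD, n = 3). GAPDH differed from this, as its 3′ probe set also read lower as cDNA, 1449 ± 64.1 against 2275 ± 106. Its 5′ probe set read 935 ± 26.5 against 2633 ± 63.7. The 3′ over 5′ ratio as cDNA was 1.55 ± 0.0353 for GAPDH and 6.87 ± 0.862 for ACTB. The 3-against-3 design cannot give an exact permutation p under 0.1. The hybridization controls are for added bacterial and phage transcripts and do not come from the sample RNA. They read a median of 5.52-fold higher on cDNA than on cRNA arrays of plain RNA (1.99 to 12.0 over 18 probe sets). On arrays of spiked RNA the median was 3.46-fold (1.30 to 6.72). They also read a median of 1.83-fold higher with spiked than with plain RNA on cRNA arrays, and 1.17-fold on cDNA arrays. Every array had a trimmed mean of 100, so these folds can reflect that scaling.

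**Figure D4:**
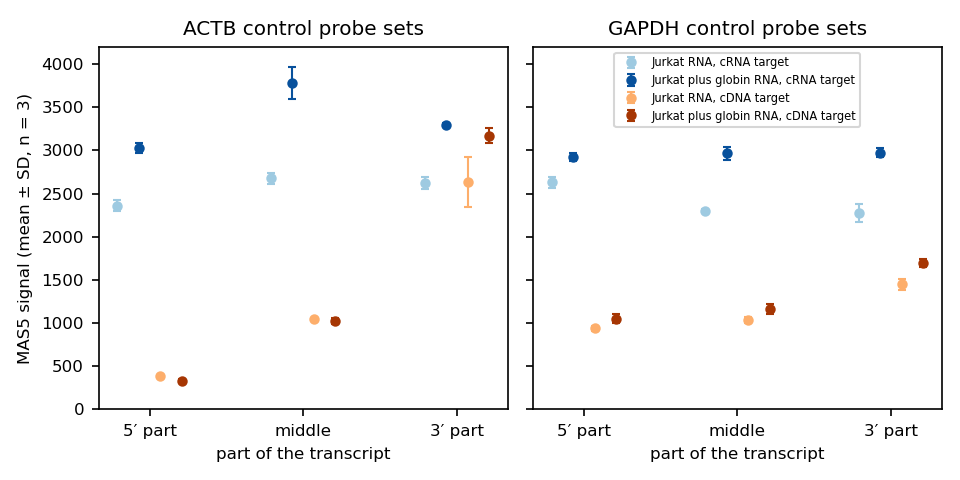
Mean MAS5 signal (arbitrary units) of the 3′, middle and 5′ control probe sets of ACTB and GAPDH in the 4 groups, with bars for SD over 3 arrays. The 5′ probe set of ACTB reads 384 as cDNA and 2360 as cRNA in plain RNA, and that of GAPDH 935 and 2633.

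In total 4689 probe sets were higher and 8577 lower as cDNA in plain RNA, of which 1791 and 2821 differed at least 2-fold. The split was 5901 and 6744 after quantile normalization, 12137 and 5264 with equal array medians, which moved the median of all probe sets by 0.347, and 474 and 17606 with hybridization control scaling, which moved it by -1.069. It was 4743 and 8678 with session as a block, and no session held both targets. Signals of the 2 targets correlated over probe sets with r = 0.892 in plain RNA. All cRNA arrays were scanned on 1 day and all cDNA arrays on another, so target and scan day cannot be told apart.

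The last question was how both targets read the spiked RNA. H3C3 had a mean of 678 ± 22.9 as cDNA against 1.35 ± 0.860 as cRNA, and RPLP2 of 2184 ± 54.9 against 78.1 ± 5.62 (SD, n = 3). UQCRC1 read 28.5 ± 3.94 against 711 ± 48.2, and LCK 357 ± 21.3 against 1847 ± 20.2. Glycolysis genes were higher for 2 of 17 and lower for 15 (2 and 15 adjusted over the list alone), with TPI1 at -2.43 and PFKL, a phosphofructokinase, at -2.24 on the log2 scale. Their shift was -0.69, with camera adjusted p = 0.0209, adjusted p = 0.302 with an estimated correlation and 0.0824 with the mean of all probe sets (shift -0.56). T cell genes were higher for 3 of 18 and lower for 13 (camera adjusted p = 0.186), and cell cycle genes higher for 5 of 26 and lower for 19 (adjusted p = 0.168), with the same counts adjusted over the list alone. Both lists passed after quantile normalization (adjusted p = 0.0286 and 1.87e-03), with equal medians (0.0354 each) and with hybridization control scaling (7.28e-03 and 1.01e-03). Histones were higher for 11 of 32 and lower for 10 (adjusted p = 0.168), and passed after quantile normalization (0.0263) and with hybridization control scaling (3.04e-06). Their split became 24 and 2 with equal medians, 14 and 3 after quantile normalization and 5 and 17 with hybridization control scaling. With that last scaling camera also called myeloid genes (9.04e-03) higher and ribosomal (3.76e-07) and proteasome genes (3.77e-05) lower than other genes, and proteasome genes were also called after quantile normalization (0.0261). Hybridization control scaling moves low signals less than high ones, so calls with it can come from this alone. Oxidative phosphorylation genes were higher for 17 of 49 and lower for 27 (adjusted p = 0.784), with a median shift of 0.06 and a mean shift of -0.14. Their split became 28 and 15 with equal medians and 0 and 49 with hybridization control scaling. Their median shift was -0.20 after quantile normalization (adjusted p = 0.0315) and -0.82 with hybridization control scaling (8.4e-07). In total 4726 probe sets were higher and 10649 lower, of which 1859 and 3361 differed at least 2-fold. The split was 6394 and 7243 after quantile normalization, which moved the median of all probe sets by 0.171, 12478 and 5292 with equal medians, which moved it by 0.479, and 906 and 17125 with hybridization control scaling, which moved it by -0.661. It was 4760 and 10737 with session as a block. The target effects in plain and spiked RNA, on different arrays, had r = 0.921 over probe sets that are not globin. They shared 3928 that were higher against 998 by chance and 7453 that were lower against 4106 by chance, while 294 went in opposite directions. Target and scan day cannot be told apart here either.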

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

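The tests on the spread of fold changes in the top 25% by signal, on random sets of probe sets and on the number of globin probe sets with a lower effect were chosen only after the result was seen.

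Globin RNA effects that differed between targets by limma are given as cDNA minus cRNA on the log2 scale. For globins the differences were -0.71 and -0.29 on HBB probe sets 209116_x_at and 211696_x_at, -2.45 for HBD, -1.81 and -0.98 for HBE1, -1.29 for HBQ1, -3.30, -2.59 and -2.77 on probe sets for both γ-globin genes, and -0.64 on 1 for both α-globin genes. Plain RNA read near 0 on these probe sets, so the sizes depend on the pseudocount. The difference on 211696_x_at changed direction with a pseudocount of 1, to 0.582, and after quantile normalization, to 0.164. Genes that rose on cRNA arrays differed by -2.33 for GIT1, -1.88 for GLUL, -2.19 for ADAP1, -2.05 for COL1A1 and -2.14 for EPOR. Genes that fell on cRNA arrays differed by 3.00 for RPS9, 2.51 for RARS1, 2.61 for EEF1D, 1.35 for AIF1, 2.00 for CASP6, 1.68 for AKTIP, 1.77 for TOR1AIP2 and 1.66 for CCNL2. Genes that rose on cDNA arrays differed by 0.44 for KCNAB2, 0.79 for VPS51, 0.73 for FLOT1 and 0.74 for DDRGK1. Genes that fell on cDNA arrays differed by -1.01 for PAGR1, -0.53 for YTHDC1, -0.38 for CYTH1, -0.89 for SLC5A3, -0.89 for ZMIZ1 and -1.16 for PRPS1. The genes other than globins were chosen for a large effect with 1 target, and that effect is part of the difference. The choice therefore partly sets the size and direction of their differences. In the difference of effects camera called the globin list (shift -1.21) and oxidative phosphorylation (shift 0.25). For the globin list this call was lost with an estimated correlation (adjusted p = 0.0529), with pseudocount 1 (0.349) and after quantile normalization (0.121).

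Human control probe sets outside the tests, listed here, read above 3.98, the highest mean among 27 control probe sets for bacterial transcripts that were not added. In plain RNA the higher of both target means was 3377 for the Alu repeat. For controls of 18S ribosomal RNA it was 835 at the 3′ part, 272 at the 5′ part and 1274 in the middle. For those of 28S ribosomal RNA it was 831 at the 5′ part and 316 in the middle, while the 3′ part read at most 1.80 and so lay below that level.

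The first pattern was that 8905 probe sets that are not globin were called on cRNA arrays. A single scaling factor per array would leave the spread of log2 fold changes among bright probe sets alike, but the interquartile range in the top 25% by signal was 2.84 times as wide on cRNA as on cDNA arrays, which argues against it as the whole cause. Effects from the 2 cRNA scan sessions, which share no array, correlated over probe sets with r = 0.801 (0.222 between the cDNA sessions), which argues against the scan session. Cross-hybridization stays open. Probe sets with the _x_at suffix rose more often than those with _at on cRNA arrays (35% against 23.8%). They also fell more often (15.0% against 12.7%), and without probe sequences this does not decide it. Competition of globin target with other RNA in labeling was not tested and stays open. No biological explanation was tested, since both RNAs held Jurkat RNA. Spiked RNA also held the added globin RNA, and whether that brought transcripts other than globin was not tested and stays open.

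The second pattern was that 7 probe sets for δ, γ, ε and θ globins rose more on cRNA than on cDNA arrays. In spiked RNA their cDNA minus cRNA median was -2.44. None of 10000 random sets of like cRNA signal was as low (lowest -1.9), which gives 0.01%, the smallest share these can give. The 7 were chosen for their rise and several belong to the same genes, so this leaves open that the added RNA held these transcripts and that the targets read them differently. With hybridization control scaling their median effect on cRNA arrays was still 3.17, which argues against one scaling factor as the cause. That 7 of the 7 had a lower effect on cDNA arrays is the pattern itself, so cross-hybridization of added globin target as cRNA stays open, without the probe sequences and the chains added.

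The 6 arrays of each 2-group comparison make 10 splits, too few for a share under 0.05. In each of the following comparisons 1 split, the real one, gave the real count. The globin RNA effect on cRNA arrays gave 8905 calls that are not globin, against 1 in the highest other split, and that on cDNA arrays 112 against 1. The target comparison gave 13266 calls in plain RNA against 0 in the highest other split, and 15375 in spiked RNA against 0. For the difference of effects, 1 of 100 drawn splits reached 5626, which excludes chance only for the labels of both targets shuffled together. The highest other split gave 5408. The 7 drawn splits that kept the cRNA groups, the real one included, gave 5095 or more, and with the cRNA arrays regrouped the highest count was 0. The count therefore follows the cRNA groups, and chance is not excluded for the cDNA groups.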

How the results depend on the processing

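Hybridization control scaling, the fits within sessions and the fit without 2 cRNA arrays with an incomplete fluidics log were chosen after seeing the data. Of 3592 checks on 151 named results, 3364 stayed on their side of the threshold with their direction, 193 lost the call, 32 gained it and 3 reversed, and 113 results held in every check. The difference of effects on HBB 211696_x_at (main -0.29) became 0.582 with pseudocount 1 and 0.164 after quantile normalization, and the effect on RPL27 on cDNA arrays -0.002 with hybridization control scaling. The ribosomal shift became -0.056 (cRNA) and -0.023 (cDNA) after quantile normalization. With hybridization control scaling it was 0.019 (cRNA) with the test pointing down, and the cDNA shifts of oxidative phosphorylation and glycolysis were -0.048 and -0.021.

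Counts are given as higher and lower. Quantile normalization gave 3605 higher on cRNA and 32 lower on cDNA arrays for the globin RNA effect. Equal array medians gave 2925 and 5884 for that effect on cRNA arrays, 3745 and 1699 for the difference, and 12137 and 5264 (plain) and 12478 and 5292 (spiked) for the targets. Without the lower 50% by signal, counts were 2786 and 3225 on cRNA arrays, 185 and 128 on cDNA arrays, 2292 and 2154 for the difference, so that the larger side turned for the first and last of these, and 5762 lower for the targets in spiked RNA. With fewer probe sets tested a count can also fall. On cDNA arrays eBayes without trend gave 37 and 29, only the arrays compared 12 and 1, the replicate block 42 and 28, and the fit without the 2 arrays 29 and 25. Hybridization control scaling gave 1606 and 12724 (cRNA), 13 and 891 (cDNA), 9776 and 920 (difference), 474 and 17606 (targets, plain) and 906 and 17125 (targets, spiked). Within sessions the counts were 3453 and 2195 and 2941 and 2014 (cRNA), and 9 and 1 and 10 and 0 (cDNA, limma; 833 and 985, and 1205 and 924, at an unadjusted p under 0.05). The median SD between replicates was 0.148, 0.196, 0.193 and 0.213 with pseudocount 1 and 0.0339, 0.0486, 0.0344 and 0.0381 with pseudocount 64, for plain and spiked cRNA and plain and spiked cDNA arrays. Apart from fewer probe sets or arrays, the cause was not tested.

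With each array left out in turn, the globin RNA effect gave 4488 to 5463 higher and 2944 to 3391 lower on cRNA arrays. On cDNA arrays it gave 24 to 209 higher and 7 to 66 lower, with 24 without spiked cDNA replicate 2, 209 without plain cDNA replicate 3 and 7 without plain cDNA replicate 2. The difference gave 1941 to 2188 and 2696 to 3442, the targets 4443 to 4759 and 8038 to 8832 (plain) and 4608 to 4729 and 10048 to 10543 (spiked), and the difference in size 0.214 to 0.235. With the replicate block the cell cycle list in plain RNA, cDNA against cRNA, had an adjusted p of 0.0511 (main 0.048). Replicate numbers did not pair the samples, since residuals of the 18 pairs with 1 number correlated at -0.042 to 0.01. With session as a random effect the estimated correlation was -0.0491. For the difference, the arrays compared are all 12, so that alternative was not run. The number of arrays limits the precision, and without detection calls signal cannot be told from background.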

Other observations

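The choice of the probe set without a symbol and the scalings tried on the third pattern were made only after the values were seen.

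A probe set without a gene symbol, 217572_at, read 0.533 ± 0.111 in plain and 157 ± 13 in spiked RNA as cRNA (SD, n = 3) and rose with limma (adjusted p = 1.74e-12). As cDNA it read 1.38 ± 1.22 and 0.37 ± 0.227, which did not pass. No fold is given, since plain RNA read near 0.

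The third pattern was that probe sets of 1 gene moved in opposite directions between targets. Of 4310 genes with several probe sets, 1128 (26.2%) had at least 1 higher and 1 lower as cDNA in plain RNA, among them LSM4, RPS10, RPL37A and ARF6, against 1087 after quantile normalization, 1171 with equal array medians and 236 (5.48%) with hybridization control scaling. On the arrays of spiked RNA 80.7% of the 1128 genes kept both directions (75.4% to 83.5% with these scalings), which argues against noise between arrays, and among probe sets in the upper 50% by signal 35.5% of genes were split (7.49% with hybridization control scaling), which argues against low signal. What else could part the probe sets of a gene was not tested and stays open. No biological explanation was tested, since both targets came from the same RNA.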
